A study of Mus musculus with 20 samples.

How the data were processed

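H3K27ac was measured by chromatin immunoprecipitation and sequencing in RAW264.7 cells that, per the labels, were fixed with 1% formaldehyde and sequenced as single-end reads of 50 bp. The 20 samples comprise 10 immunoprecipitated libraries, each with 1 peak list, and 10 input libraries without a list, which were not analysed here. Per the submitters' processing notes, reads were checked with FastQC and aligned with Bowtie2 to mm10 (GRCm38), and peaks were called with MACS2, with no versions given. The filters, the peak calling settings and whether each list was called against its own input are not stated.

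Each deposited list is a broad-peak table whose columns were identified from their layout and values. The authors' score is 10 times the -log10 q, written as a whole number. The deposited fold enrichment is a ratio of signal over the caller's local background on a linear scale. The deposited p and q values of each peak are on a -log10 scale. The score, fold, p and q of each peak are the authors' and were used only to describe, rank or filter peaks within a list, never as tests between groups. The lists hold no counts, so the depth of each library is unknown and no counting interval can be given.

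Groups and replicate numbers came from the labels. Consensus regions were stretches covered by peaks of at least 2 of the 10 libraries, and a library held a region if its peaks covered at least 1 bp of it. This gave 21013 regions, of which 4020 were held by all 9 libraries of the 3 groups. Gained meant held by all 3 libraries of the first group and by 0 of 3 of the second, and lost meant the reverse. A comparison of 3 against 3 allows no p per region under 0.1, so counts were compared with other splits of the libraries. They were also compared with 1000 simulated sets in which each region kept its strength and each library its detection rate, with no region-specific effect. Peak number and covered length were compared with two-sided exact permutation tests of group means.

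Genes were the 21887 protein-coding genes of a GRCm38 annotation, the authors' build. The annotation gives no strand, so distances run to either end of a gene in place of its transcription start. A gene-end peak lay within 1 kb of either end, and a region's nearest gene had to lie within 100 kb. For the gene-level test each list was reduced to its peaks with the highest -log10 p until its covered length equalled that of the shortest list, 3.44 Mb. The base pairs covered within 25 kb of either gene end were then counted and transformed as log2 of the length plus 500 bp. Genes with a mean under 500 bp over the 9 libraries were left out, which left 4155. limma (moderated linear model with a trended prior) fitted the 3 groups together, and p-values were adjusted by the Benjamini-Hochberg method. Of 14 gene lists written in advance, 323 of 325 members were found in the annotation. The lists were tested with camera (preset correlation 0.01, and an estimated correlation) for the 10 lists with at least 3 tested genes, and with two-sided Fisher's exact tests against the 10378 genes nearest to any consensus region. They cover NFATc1 axis transcription factors, the NF-kB pathway, osteoclast function, inflammatory cytokines, interferon response, macrophage identity, dendritic cells, MYC and ribosome biogenesis, BET-related genes, the cell cycle, housekeeping, and markers of lymphocytes, of fibroblasts and osteoblasts, and of tissues not in the culture.

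Genes and regions were named by a rule fixed in advance. It took the 10 strongest gained and lost regions of each comparison, ranked by the lowest -log10 p among the libraries that hold them, genes past the limma threshold, list members past it when adjusted over the list alone, and 29 genes always given. A few genes and regions that this rule names are not reported here. List members nearest to a gained or lost region were named as part of the list tests. The groups, tests, lists, this rule and the other settings to be tried were fixed before the data were examined, except that the sizes of the deposited files were known and showed that RANKL replicate 2 was far longer than the others. The settings fixed in advance were one covered length for all lists, a -log10 q of at least 5, 50% coverage of a region, presence in 2 of 3 libraries, other consensus rules and lists without the libraries numbered 2. At gene level they were other windows, pseudocounts, filters and rankings and a replicate block. Each library was also left out in turn. Combinations of these and a window over the whole gene were added after seeing the data. All windows were counted from gene ends.

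The region code was tested on simulated lists, where it found 100 of 100 planted gains and 50 of 50 planted losses. The gene-level test was tried on changes planted in simulated normal values, drawn independently with each gene's mean and residual SD (median 1.18, log2 scale). It recovered 10% of changes of 2 log2 units, 82% of changes of 4 and 100% of changes of 8, with 9 false calls. A change of 8 is larger than the windows around genes allow, so recovery at that size does not bear on these lists. These values lacked correlation between genes and single odd libraries, so recovery in the real lists may differ. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.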

Results

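Histone H3 lysine 27 acetylation (H3K27ac), a mark of active promoters and enhancers, was mapped by chromatin immunoprecipitation and sequencing in RAW264.7 cells. This mouse macrophage line of monocytic origin can be driven towards osteoclasts, the bone-resorbing cells, by the cytokine RANKL. Cells were untreated, given RANKL at 50 ng/ml for 4 h, given RANKL together with the BET bromodomain inhibitor I-BET at 500 nM for 4 h, or given I-BET alone. BET proteins bind acetylated histones and support transcription. The first 3 groups had 3 libraries each and I-BET alone had 1 library, numbered 3. Each of these 10 libraries came with 1 list of peaks on the mouse GRCm38 build, while the other 10 samples, which were sequenced input DNA, had no list and were not analysed here. The lists give no read counts, so the sequencing depth is unknown. The labels state no separate cultures, so p-values measure only the spread between these samples, which may be technical.

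Lists held 16364, 9893 and 13677 peaks in untreated replicates 1, 2 and 3 and 17794, 141905 and 16917 peaks in the RANKL replicates. RANKL+I-BET lists held 17643, 6041 and 13613 peaks, and the I-BET list held 13368. The covered length was 16.1, 7.79 and 19.5 Mb in untreated cells, 23.7, 184.6 and 25.9 Mb with RANKL, 23.0, 3.44 and 20.6 Mb with RANKL+I-BET and 19.6 Mb with I-BET alone. RANKL replicate 2 stood apart from the other libraries in content as well as in length. Only 14.2% of its peaks lay within 1 kb of a gene end, against 40.7% to 54.0% in the other libraries. It placed peaks at gene ends of 13 of 14 lymphocyte marker genes, 8 of 14 fibroblast and osteoblast marker genes and 13 of 18 marker genes of tissues absent from the culture. The other libraries did so at 0 or 1 lymphocyte markers and at 0 of the other markers. RANKL+I-BET replicate 2, the shortest list, held no peak with a -log10 q under 2, whereas such peaks made up 15.8% to 61.8% of every other list.

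The first question was whether lists differed in extent between groups. The mean peak number was 58872 ± 71910 with RANKL and 13311 ± 3251 without (SD, n = 3 each; difference 45560.7, two-sided exact permutation p = 0.1). The mean covered length was 78.0 ± 92.2 Mb with RANKL and 14.4 ± 6.02 Mb without (difference 63.6 Mb, n = 3 each, exact p = 0.1). With RANKL+I-BET the means were 12432 ± 5890 peaks and 15.7 ± 10.6 Mb (n = 3). This lay below RANKL by the signed differences of -46439.7 peaks (exact p = 0.2) and -62.4 Mb (exact p = 0.1). Against untreated cells the differences were -879 peaks (exact p = 0.9) and 1.20 Mb (exact p = 0.8). An exact test of 3 against 3 libraries cannot go below 0.1. Replicate 2 carried most of the RANKL excess, since without the libraries numbered 2 RANKL exceeded untreated by 2335 peaks and 7.01 Mb, and RANKL+I-BET differed from RANKL by -1727.5 peaks and -3.03 Mb.

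**Figure D1:**
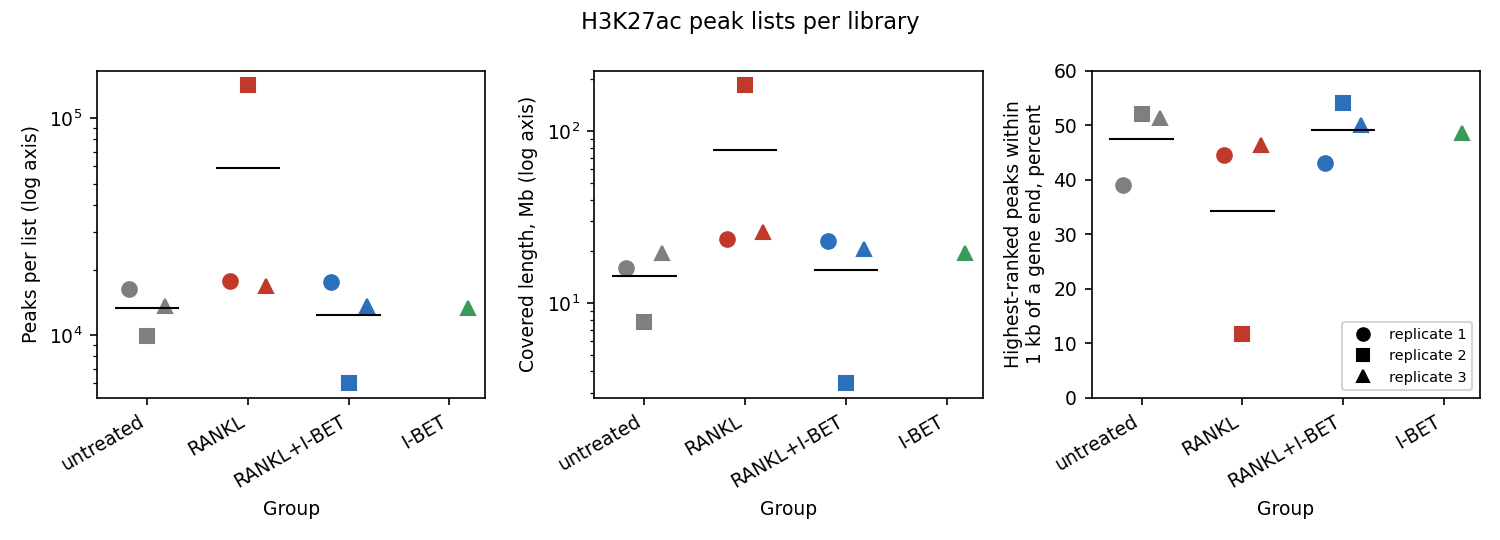
Number of peaks (log axis), covered length in Mb (log axis) and percent of the highest-ranked peaks of each list within 1 kb of a gene end, with one point per library and horizontal lines at the mean of each group of 3. RANKL replicate 2 lies above all other libraries in the first 2 panels and at 11.7% in the last, where the other libraries span 39.1% to 54.0%.

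The comparison of RANKL with untreated cells asks where acetylation appears in the first hours of osteoclast commitment. Regions present in all 3 RANKL lists and in no untreated list, here called gained, numbered 719, and no region had the reverse pattern, here called lost. Interferon-induced genes were among those with a gained region at the gene itself: Cmpk2, a mitochondrial nucleotide kinase, Isg15, a ubiquitin-like protein, and Isg20, an RNA exonuclease. Gained regions also lay in Il1rn, which encodes the interleukin-1 receptor antagonist, in the chemokine gene Ccl4 and in Cdk6, a cell cycle kinase. The 4 strongest gained regions lay in Aif1, a calcium-binding protein of macrophages, in Mon1a, a regulator of vesicle traffic, in Asrgl1 and in Commd1, an inhibitor of NF-kB.

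The Aif1 region (chromosome 17, 35172191 to 35173646) had a fold enrichment of 8.02, 6.02 and 4.23 in RANKL replicates 1, 2 and 3. The region inside Mon1a (chromosome 9, 107887956 to 107888424) had a fold enrichment of 4.56, 10.3 and 4.99. The Commd1 region (chromosome 11, 22929885 to 22930680) reached 8.55, 7.08 and 4.61. The 10 strongest also included regions inside Ext1, which encodes a heparan sulfate polymerase, Thra, the thyroid hormone receptor alpha gene, Notch2, a cell-surface receptor, and Utrn, a cytoskeletal linker. Regions beside Itpr3, a calcium release channel (9594 bp away), and Ccdc9 (10044 bp away) completed them. The 719 regions had a median width of 813 bp, against 1214 bp for all 21013 regions found in at least 2 libraries. Of the gained regions 41.0% lay within 1 kb of a gene end, against 41.4% of all regions. They were nearest to 663 genes, with 3 regions each at Creb5, Prkch and Utrn, and 25 had no gene within 100 kb. A peak appeared within 1 kb of the ends of 326 genes in all RANKL libraries and no untreated library, and of 0 genes in the reverse pattern.

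Around the genes that drive osteoclast formation, covered length within 25 kb of either gene end was compared as deposited. Nfatc1, the master regulator of osteoclast differentiation (chromosome 18, 80606205 to 80713071), had 6.69, 4.53 and 11.9 kb in untreated replicates and 11.4, 69.1 and 15.7 kb with RANKL. Traf1, an adaptor in TNF receptor signalling, had 4.43, 2.47 and 3.86 kb in untreated replicates and 6.07, 28.0 and 6.05 kb with RANKL. Nfkb2, an NF-kB subunit, had 1.05, 0.161 and 2.12 kb untreated and 3.04, 35.0 and 3.39 kb with RANKL. Acp5, the tartrate-resistant acid phosphatase of osteoclasts, had 1.26, 0.719 and 2.20 kb untreated and 3.41, 27.1 and 2.87 kb with RANKL. Dcstamp, needed for osteoclast fusion, had 0.854, 0.714 and 4.33 kb untreated and 2.54, 17.4 and 6.63 kb with RANKL, and its partner Ocstamp had 0.250, 0.299 and 1.83 kb against 1.78, 23.0 and 4.73 kb. Ctsk, the collagen-degrading cathepsin K, was already covered in untreated cells (15.8, 8.59 and 14.1 kb, against 17.1, 19.3 and 16.3 kb). The vacuolar proton pump gene Atp6v0d2 had 7.15, 0.481 and 0.963 kb untreated and 1.95, 1.06 and 2.51 kb with RANKL. Fos, which acts upstream of Nfatc1, had 11.8, 12.6 and 12.5 kb untreated and 15.2, 26.8 and 13.0 kb with RANKL. Myc, a growth-promoting transcription factor, was listed at 0 in every untreated library and at 0, 6.47 and 3.06 kb with RANKL. Prdm1, a repressor that favours osteoclast formation, the gelatinase gene Mmp9 and the integrin gene Itgb3 were covered in RANKL replicate 2 alone, at 6.92, 29.5 and 10.8 kb.

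Irf8, which restrains osteoclast formation, had 5.75, 1.22 and 2.28 kb untreated and 5.17, 43.0 and 5.30 kb with RANKL. Bcl6, another such repressor, had 3.10, 0 and 4.74 kb untreated and 5.05, 16.9 and 6.50 kb with RANKL. The myeloid regulator Spi1 had 15.3, 10.9 and 18.3 kb untreated and 18.5, 52.2 and 20.2 kb with RANKL. Csf1r, the macrophage growth factor receptor, had 12.2, 7.74 and 15.1 kb untreated and 14.3, 47.2 and 16.8 kb with RANKL. Relb, an NF-kB subunit, had 1.36, 0.392 and 1.19 kb against 2.21, 45.4 and 1.62 kb, and Tnfaip3, an NF-kB inhibitor, had 0.694, 0.208 and 1.81 kb against 2.36, 9.0 and 1.54 kb. The cytokine gene Tnf had 21.3, 7.52 and 15.3 kb against 21.6, 36.5 and 24.8 kb, and the chemokine gene Ccl3 had 6.54, 1.96 and 4.85 kb against 6.97, 9.05 and 7.56 kb. Of the housekeeping genes, Gapdh had 3.29, 4.80 and 4.91 kb against 5.77, 30.9 and 5.58 kb and Actb had 6.71, 5.16 and 11.4 kb against 13.9, 35.8 and 14.4 kb. The liver gene Alb was listed at 0 in every library, and the muscle gene Myod1 was covered only in RANKL replicate 2, at 12.6 kb. These lengths stand beside total covered lengths that were longer in each RANKL library than in the untreated library of the same number.

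**Figure D2:**
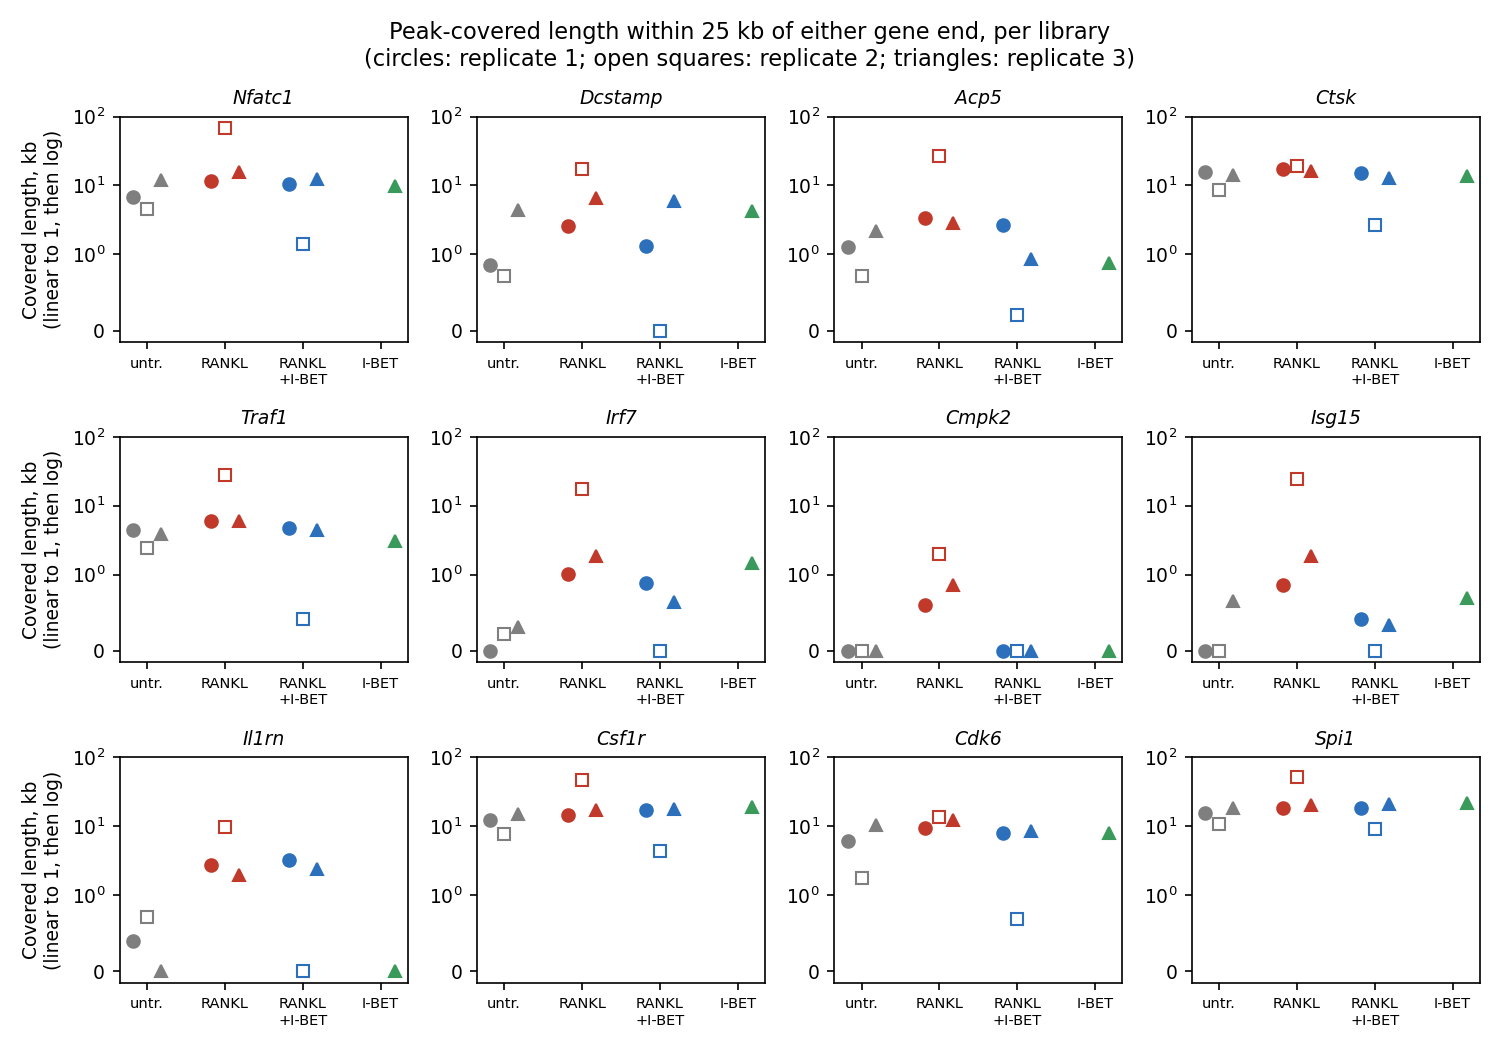
Peak-covered length in kb within 25 kb of either gene end for 12 genes, on an axis linear to 1 kb and logarithmic above, with one point per library. RANKL replicate 2 (open square) lies at 69.1 kb for Nfatc1, where the other RANKL libraries lie at 11.4 and 15.7 kb, and Cmpk2 is listed at 0 in every library outside the RANKL group.

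Over all genes, those with a peak within 1 kb of a gene end numbered 7086 ± 1163 in untreated and 11470 ± 4084 in RANKL libraries (SD, n = 3 each), and 7671 and 9112 without the libraries numbered 2. By gene group, members with a peak within 1 kb of a gene end numbered 9 ± 6 in untreated and 19.3 ± 2.52 in RANKL libraries (SD, n = 3 each) among 26 interferon response genes. The single libraries held 9, 3 and 15 untreated and 17, 22 and 19 with RANKL. Among 30 osteoclast function genes the numbers were 15.0 ± 1.73 and 21.0 ± 6.08 (14, 14 and 17 untreated and 17, 28 and 18 with RANKL). Among 24 transcription factors of the RANKL and NFATc1 axis they were 15.7 ± 1.16 and 19.7 ± 3.06 (15, 15 and 17 untreated and 19, 23 and 17 with RANKL). RANKL replicate 2 carried most of the osteoclast excess, being the only library with a peak at 6 of those members, and at 4 of the NFATc1 axis. Among 26 NF-kB pathway genes they were 22.0 ± 1.00 and 24.7 ± 1.16, among 29 macrophage identity genes and repressors 16 ± 3 and 21.7 ± 2.89, and among 30 inflammatory cytokines and chemokines 6.67 ± 1.16 and 13.3 ± 9.24. The last excess came mostly from the same library, as the single libraries held 6, 8 and 6 untreated and 8, 24 and 8 with RANKL. It also carried most of that of the 20 dendritic cell genes (5 ± 1.73 and 10 ± 6.08), with 7, 4 and 4 untreated and 7, 17 and 6 with RANKL. Means were 23.0 ± 2.00 and 27.3 ± 2.52 for the 30 MYC and ribosome biogenesis genes and 15.0 ± 0.0 and 16.3 ± 0.577 for the 18 BET-related genes. The 24 cell cycle genes gave 18.0 ± 5.20 and 24.0 ± 0.0, and the 20 housekeeping genes 18.0 ± 1.73 and 19.0 ± 0.0. Among genes nearest to gained regions, Fisher's exact test over 14 lists gave its smallest p for macrophage identity (Fcgr1, Lyz2, Mef2c, Rbpj and Runx1, 5 of 28 members near any region, p = 0.0303, adjusted p = 0.424). Interferon response genes came to 3 of 21 (Fisher's exact p = 0.147, adjusted p = 0.687). None of the NFATc1 axis genes and none of the osteoclast function genes were nearest to a gained region.

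With lists reduced to their highest-ranked peaks at one covered length, limma called 0 of 4155 genes for RANKL against untreated at an adjusted p under 0.05, and 160 genes had an unadjusted p under 0.05. The smallest adjusted p was 0.882, the median log2 difference over all genes was -0.25, and 0 list members passed when adjusted over the list alone. A test of gene lists on the same fit (camera) placed macrophage identity genes lower with RANKL than other genes. Of the 16 members tested 14 were lower, with a median log2 difference of -1.30 (adjusted p = 0.0137), and the call was lost at adjusted p = 0.406 with an estimated correlation. The other 9 lists tested gave no call, the nearest being the NFATc1 axis (7 of 9 lower, median -1.36, adjusted p = 0.0554, and adjusted p = 0.406 with an estimated correlation). For the NF-kB, inflammatory and housekeeping lists the median was negative although camera ranked them above other genes, and for cell cycle genes the median (0.56) and the mean (-0.07) differed in sign. Without the libraries numbered 2 the macrophage list had a median of -0.08 over 26 members (adjusted p = 0.853), and 4 genes passed when adjusted over the list alone (adjusted p between 0.0302 and 0.0422, and 0.919 over all genes). Their log2 differences were -2.80 for Pcna and -2.97 for Cdc20, of the cell cycle list, and -1.66 for B2m and -2.69 for Ppia, of the housekeeping list. With the replicate block 0 of the 4 passed (limma, smallest adjusted p over the list alone 0.0513 for the cell cycle and 0.0640 for housekeeping). With the same libraries and lists as deposited and median-centred, 0 passed either (smallest 0.362 and 0.774).

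With all lists at one covered length the region counts turned to 6 gained and 89 lost, without the libraries numbered 2 they were 1100 and 45, and with both changes they were 563 and 1266. At one covered length RANKL replicate 2 shared 0.0061 and 0.0041 of its joint covered length with RANKL replicates 1 and 3. RANKL replicates 1 and 3 shared 0.0787 of theirs. The low sharing of RANKL replicate 2 limits the regions that all RANKL libraries can hold. Lost regions also outnumbered gained ones without the libraries numbered 2 (1266 and 563), so that library alone does not account for the turn. Leaving out untreated replicate 1, untreated replicate 3, RANKL replicate 1 or RANKL replicate 3 moved the gained count to 1368, 2083, 1761 or 1825, and 19 regions were lost without untreated replicate 2.

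**Figure D3:**
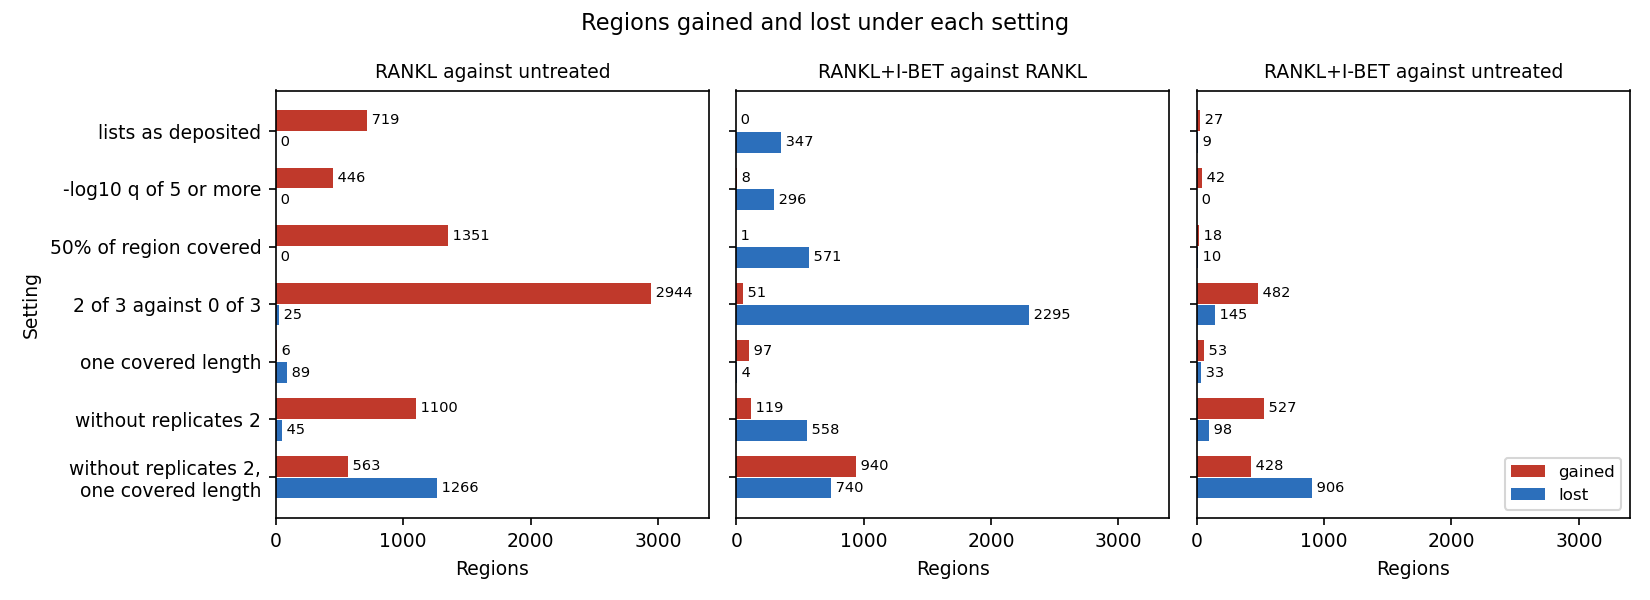
Numbers of regions gained (red) and lost (blue) in each comparison under 7 settings, as bars from 0. The excess of gained regions with RANKL (719 against 0 with the lists as deposited) turns into an excess of lost regions (6 against 89) when all lists have one covered length. At that length the list of RANKL replicate 2 shares little with the other RANKL lists, which limits the regions that every RANKL list can hold.

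The comparison of RANKL+I-BET with RANKL asks which acetylation depends on BET proteins. Regions held by all 3 RANKL libraries and by no RANKL+I-BET library numbered 347, and no region had the reverse pattern. Sets simulated with no region-specific effect gave 471.4 such regions on average (95% between 430 and 513). The reverse pattern came to 0.408 regions on average in these sets (95% between 0 and 2). Among the 347 were regions at the interferon-response genes Cmpk2 and Irf7, a transcription factor of the interferon response. Others lay at Cdk6 and at Ppargc1b, a coactivator of mitochondrial biogenesis. The strongest lost regions lay beside Itpr3 and within Commd1, Ext1, Thra and Notch2.

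The Itpr3 region (chromosome 17, 27051114 to 27052183, 4818 bp from the gene) had a fold enrichment of 4.51, 8.67 and 7.12 in the RANKL replicates and was held by 1 untreated library. The Ext1 region (chromosome 15, 53140221 to 53140763) reached 5.22, 3.24 and 3.66, and the Notch2 region (chromosome 3, 98087249 to 98088118) reached 4.57, 2.63 and 3.85. Both were absent from the I-BET library. The Thra region (chromosome 11, 98741800 to 98742211) reached 5.23, 7.70 and 5.13 and was present with I-BET alone. Further regions lay at Jarid2, a partner of the Polycomb complex (56541 bp away), Kidins220, Ppargc1b, Alg11, a mannosyltransferase, and Syt11, a vesicle protein (11275 bp away). The Ppargc1b region (chromosome 18, 61322360 to 61323968) had a fold enrichment of 6.01, 2.67 and 4.08 with RANKL. It was present with I-BET alone, as was the Kidins220 region. The 347 regions were nearest to 320 genes, with 3 regions each at Arsb and Grb2, and 34.6% lay within 1 kb of a gene end.

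Cmpk2 was listed at 0 in every untreated, RANKL+I-BET and I-BET library and at 0.602, 1.96 and 0.861 kb with RANKL. Irf7 had 1.04, 17.7 and 1.87 kb with RANKL, 0.885, 0 and 0.635 kb with RANKL+I-BET and 1.49 kb with I-BET alone. Cdk6 had 9.36, 13.5 and 12.1 kb with RANKL and 7.91, 0.689 and 8.47 kb with both agents. Nfatc1 had 10.5, 1.41 and 12.5 kb with RANKL+I-BET, Acp5 2.66, 0.202 and 0.940 kb, Dcstamp 1.32, 0 and 5.89 kb, Traf1 4.70, 0.415 and 4.38 kb and Ctsk 15.3, 2.64 and 12.9 kb. Myc had 1.39 kb in RANKL+I-BET replicate 1 and was listed at 0 in the other RANKL+I-BET libraries. The BET gene Brd2 had peaks at its ends in all 3 RANKL+I-BET libraries, with 7.84, 3.26 and 8.36 kb. Hexim1, an inhibitor of the elongation factor P-TEFb, had 7.22, 27.1 and 9.10 kb with RANKL and 7.13, 1.84 and 6.46 kb with both agents. Covered length in total was shorter in each RANKL+I-BET library than in the RANKL library of the same number.

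Members with a gene-end peak came to 10.3 ± 6.43 of 26 interferon response genes with RANKL+I-BET (SD, n = 3; 15, 3 and 13 in the single libraries), against 19.3 ± 2.52 with RANKL. They came to 14.7 ± 4.04 of 30 osteoclast function genes, 15.3 ± 2.08 of 24 NFATc1 axis genes, 19.3 ± 8.08 of 26 NF-kB genes, 8 ± 3 of 30 inflammatory genes and 14.7 ± 6.81 of 29 macrophage genes. The dendritic, MYC, BET-related, cell cycle and housekeeping lists gave 4.67 ± 2.52, 21.3 ± 5.69, 13.3 ± 2.89, 18.7 ± 9.24 and 16.3 ± 4.62 members. RANKL+I-BET replicate 2, the shortest list, carried much of these differences, with 24, 10 and 24 NF-kB, 24, 8 and 24 cell cycle and 19, 11 and 19 housekeeping genes in the single libraries. In replicates 1 and 3 these 3 lists had the same numbers with RANKL. Over all genes the mean was 6979 with RANKL+I-BET. A gene-end peak was present in every RANKL and no RANKL+I-BET library for 121 genes, Cmpk2 and Irf7 among them, and for 0 genes in the reverse. Nearest to lost regions were 2 of 21 interferon genes (Fisher's exact p = 0.136, adjusted p = 0.950) and 2 of 18 BET-related genes (Fisher's exact p = 0.105, adjusted p = 0.950). At one covered length limma called 0 of 4155 genes, with 160 at an unadjusted p under 0.05 and a smallest adjusted p of 0.888, against a median log2 difference of 0.28 over all genes. Camera called 0 of the 10 lists (smallest adjusted p = 0.467), and its direction was opposite to the median for the NF-kB list and to the mean for the inflammatory list. No list member passed when adjusted over the list alone, although without the libraries numbered 2 the antigen presentation component B2m (2.03) and the isomerase gene Ppia (2.72) did so, at an adjusted p of 0.0145 each (0.540 over all genes). Both passed with the replicate block too (limma, adjusted p = 0.0307 each), and neither with these libraries and lists as deposited and median-centred (limma, smallest adjusted p over the list alone 0.949).

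At one covered length 97 regions were gained and 4 lost, with RANKL replicate 2 again sharing little with the other RANKL lists. The counts were 119 and 558 without the libraries numbered 2, and 940 and 740 with both changes. In 95% of sets simulated without the libraries numbered 2, 73.0 to 111 regions were gained and 471 to 552 lost. The observed 119 and 558 both lay above these ranges and below the highest simulated sets (122 and 575). Leaving out RANKL replicate 1, 2 or 3 moved the lost count to 1342, 554 or 1247, and leaving out RANKL+I-BET replicate 1 or 3 moved it to 1599 or 542, while 45 regions were gained without RANKL+I-BET replicate 2.

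The comparison of RANKL+I-BET with untreated cells asks what differs when both agents are present. It separated the fewest regions, with 27 gained and 9 lost, both inside the range of sets simulated with no region-specific effect (95% between 13 and 30 gained and between 3 and 14 lost). These sets treat libraries as independent, so the match decides little. RANKL+I-BET replicate 2, the shortest list, limits the regions that every RANKL+I-BET library can hold. Gained regions lay in Ppard, a nuclear receptor, in App, the amyloid precursor, in Ptk2b, a kinase of the cytoskeleton, in Ptpn12, a phosphatase, and in Creb5, a transcription factor. Lost regions included those within Gsdme, a gasdermin, and Rapgef1, an exchange factor for small GTPases.

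The Ppard region (chromosome 17, 28232714 to 28233472) had a fold enrichment of 5.28, 4.78 and 7.25 in the RANKL+I-BET replicates and was also held by all 3 RANKL libraries but not by I-BET alone. The App region (chromosome 16, 84967334 to 84967906) reached 7.37, 4.69 and 2.70, and the Creb5 region (chromosome 6, 53447860 to 53449241) reached 3.99, 4.48 and 2.21. The Ptk2b region (chromosome 14, 66213472 to 66214831) reached 3.45, 4.09 and 2.95. Regions at Gsap (43687 bp away), Ccdc32, Med21, a Mediator subunit (24013 bp away), Ttc7b, Ptpn12 and Olfml3 (6717 bp away) completed the 10 strongest. The gained region nearest to Nfkbiz, an NF-kB cofactor (chromosome 16, 55733624 to 55734894, 76480 bp away), was held by all RANKL libraries too. The lost Gsdme region (chromosome 6, 50261148 to 50262424) had a fold enrichment of 2.65, 2.12 and 2.54 in untreated replicates and was held by 2 RANKL libraries. Further lost regions lay within Ctnnbl1, Btbd2, Gipc2, Rapgef1, Zfp81 and Lrrc27.

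Il1rn had 0.391, 0.707 and 0 kb untreated, 2.73, 9.56 and 1.94 kb with RANKL and 3.23, 0 and 2.34 kb with both agents. Gene-end peaks were gained at 8 genes and lost at 3. No list passed Fisher's exact test after adjustment among gained or lost genes (smallest adjusted p = 0.217). At one covered length limma called 0 of 4155 genes, with 61 at an unadjusted p under 0.05 and a smallest adjusted p of 1, and no list member passed when adjusted over the list alone. Camera called 0 of the 10 lists, macrophage identity coming nearest (10 of 16 lower, median -0.51, adjusted p = 0.371), and for the inflammatory list the median and its direction differed in sign.

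Without the libraries numbered 2 the counts were 527 gained and 98 lost, and the inflammatory list was enriched among the gained genes (Ccl2, Ccl4, Cd80, Il1rn and Ptgs2, 5 of 13 members, Fisher's exact p = 0.000244, adjusted p = 0.00342). Leaving out untreated replicate 1, untreated replicate 3, RANKL+I-BET replicate 2 or RANKL+I-BET replicate 3 moved the gained count to 73, 128, 430 or 77, and leaving out untreated replicate 1, 2 or 3 or RANKL+I-BET replicate 1 or 3 moved the lost count to 29, 94, 39, 152 or 16.

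The next question was what became of RANKL-gained regions when the inhibitor was present. Of the 719 regions 164 (22.8%) were held by no RANKL+I-BET library, 349 (48.5%) by 1, 192 (26.7%) by 2 and 14 (1.95%) by all 3. The region at Cmpk2 (chromosome 12, 26469011 to 26470081) and one of 2 neighbouring regions within Cdk6 (chromosome 5, 3432330 to 3433743) were held by none. So was a region 18095 bp from Actb. The other Cdk6 region (chromosome 5, 3433871 to 3435087) was held by 2, as were those in Il1rn (chromosome 2, 24345056 to 24346571), at Isg20 (chromosome 7, 78912424 to 78914429) and in Ccl4 (chromosome 11, 83657019 to 83658295). The Isg15 region (chromosome 4, 156200590 to 156201297) was held by 1, as were the regions at Runx1, a regulator of blood cell identity, Fcgr1, an antibody receptor, and Ccnd1, the cyclin D1 gene. Regions at Mef2c, Lyz2, the lysozyme of macrophages, and Rbpj, the effector of Notch signalling, were held by 2.

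Independent lists of the same sizes would share 11.9 regions between those gained with RANKL and those lost with the inhibitor, but both counts use the RANKL libraries. Libraries simulated with no region-specific effect shared 246.5 on average (95% of 1000 sets between 217 and 277), but they also had more gained regions, 995.9 on average. As a share of the gained regions this was 24.8% (95% between 22.2% and 27.5%), a range that includes the observed 22.8%. The shares held by 1 and by 2 RANKL+I-BET libraries lay outside the simulated ranges, at 48.5% against 40.4% to 46.3% and 26.7% against 27.8% to 33.3%. Without the libraries numbered 2, 319 of 1100 gained regions (29.0%) were held by no RANKL+I-BET library. There the simulated sets gave 253.1 of 1349 on average, a share of 18.8% and at most 21.8%. These sets had more gained regions than observed (95% between 1283 and 1414) and treat libraries as independent. The correlations given below between libraries used deviations from group means that include the libraries numbered 2, so they do not describe this setting. Whether dependence between libraries raises the share by as much was not tested, so the difference is left open. In other settings the observed share was 51.1% of 446 regions with peaks of -log10 q of at least 5 and 55.9% of 2944 when presence in 2 of 3 libraries was enough. No sets were simulated for these settings. The -log10 q filter also raised that share from 6.4% to 40.2% among regions held by every RANKL library and 1 untreated library.

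**Figure D4:**
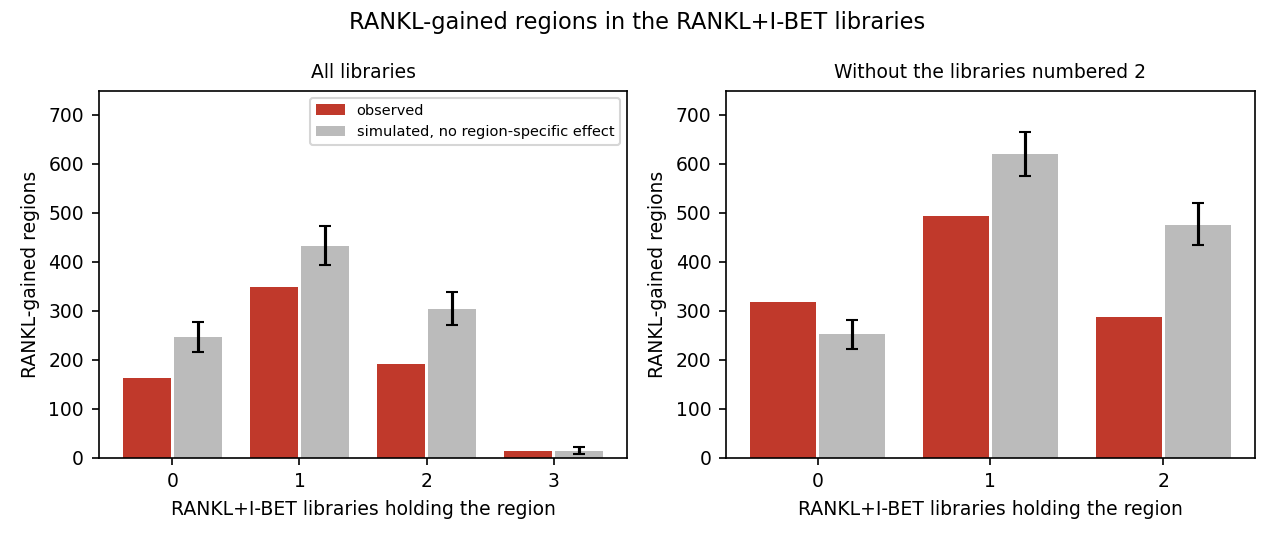
RANKL-gained regions by the number of RANKL+I-BET libraries that hold them, observed (red) and as the mean of 1000 simulated sets without region-specific effects (grey, error bars spanning 95% of the sets). With all libraries 164 regions are held by none, against 246.5 simulated, and without the libraries numbered 2 the numbers are 319 and 253.1. The simulated sets had more gained regions in total (995.9 against 719, and 1349 against 1100), so the bars compare counts and not shares.

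I-BET alone was represented by 1 library, so its own spread could not be measured and no test was made. Its list was set beside those of replicate 3 from the other groups. Its peaks overlapped untreated replicate 3 at 86.8%, RANKL replicate 3 at 94.0% and RANKL+I-BET replicate 3 at 87.7%. With the 4 lists at one covered length the order turned round, with 87.0%, 68.0% and 81.6%. Among 17983 regions of these 4 lists, 3811 were present with RANKL and absent from untreated cells, and 450 had the reverse pattern. Of the 3811 regions 27.9% were present with I-BET alone and 29.8% with both agents. I-BET alone had 1647 regions absent from untreated cells and lacked 1928 that untreated cells had. It held 218 (30.3%) of the 719 RANKL-gained regions, those at Isg15 and Ccl4 included and those in Il1rn, Cmpk2 and Isg20 not, and 86 (24.8%) of the 347 lost ones. Gene-end peaks marked 16 of 26 interferon response genes, Irf7 among them, against 15 in untreated replicate 3. With the 4 lists at one covered length, 2327 regions were present with RANKL and absent from untreated cells and 4092 had the reverse pattern.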

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

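Settings that combine the omission of the libraries numbered 2 with another change, and the window over the whole gene, were chosen only after the results were seen, and all others were planned. At gene level limma called 0 genes in all 3 comparisons under each of the 21 alternatives per comparison, including the replicate block, other windows, pseudocounts and filters and each library left out, where the smallest adjusted p was 0.223. Unadjusted p-values under 0.05 numbered between 21 and 788 over those settings. Replicate numbers were not taken as pairs in the main tests, since the labels state no pairing. The lists do show some likeness by number. As deposited, libraries of the same number shared on average 0.4326 of their joint covered length, against 0.3161 for libraries of the same group. The ranges overlapped (0.01684 to 0.6689 and 0.09664 to 0.6381). The exact tests and the simulated sets do not allow for such likeness, and its source was not tested. Correlations were taken over genes between libraries of different groups, on the log2 covered length as its deviation from the mean of the group. In the lists of equal covered length used by limma, the correlations between libraries of the same number lay between 0.009 and 0.247 and those of other pairs between -0.165 and 0.057. In the lists as deposited, which the region counts and simulated sets used, they lay between 0.141 and 0.567 and between -0.514 and 0.38. The depth of the libraries is unknown, and in values simulated with the residual SDs planted changes of 2 log2 units were recovered in 10% of cases. Differences in peak number and covered length kept their direction except that of RANKL+I-BET against untreated in peak number, which reversed from -879 to 1754.33 with a -log10 q of at least 5 and to 607.5 without the libraries numbered 2. Regions drawn from any 1 library or merged over gaps of up to 1 kb gave counts within 1.5 times the reported ones.

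Region counts moved by over 1.5 times in the cases below. The cause was not tested, except where a setting's construction shows it, as where presence in fewer libraries is asked for. With all lists at one covered length, 6 regions were gained and 89 lost for RANKL against untreated, 97 and 4 for RANKL+I-BET against RANKL, and 53 and 33 for RANKL+I-BET against untreated, and 50% of the gained regions were held by no RANKL+I-BET library. At that length the RANKL replicate 2 list shared few bases with any other list, which limits the regions that every RANKL library can hold. With a -log10 q of at least 5, 446 regions were gained with RANKL, 8 were gained for RANKL+I-BET against RANKL, 42 were gained and 0 lost for RANKL+I-BET against untreated, and the share held by no RANKL+I-BET library was 51.1%. With 50% of a region covered, 1351 regions were gained with RANKL, and 1 was gained and 571 were lost for RANKL+I-BET against RANKL. With presence in 2 of 3 libraries the counts were 2944 and 25, 51 and 2295, and 482 and 145 for the same 3 comparisons, and the share was 55.9%.

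Without the libraries numbered 2 the gained and lost counts were 1100 and 45 for RANKL against untreated, 119 and 558 for RANKL+I-BET against RANKL, and 527 and 98 for RANKL+I-BET against untreated. The share held by no RANKL+I-BET library was 29.0%. There 1 of Fisher's list tests passed, where 0 had passed with all libraries. Without these libraries and with one covered length, 1266 regions were lost for RANKL against untreated, 940 were gained and 740 lost for RANKL+I-BET against RANKL, 428 were gained and 906 lost for RANKL+I-BET against untreated, and the share was 40.7%. Without them and with a -log10 q of at least 5 the counts were 1242 and 41, 390 and 871, and 692 and 57. The single call of camera was kept with the replicate block. It became 0 calls with an estimated correlation and in all 4 settings without the libraries numbered 2.

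Leaving out each library in turn gave between 841 and 2083 gained and between 1 and 19 lost regions for RANKL against untreated. For RANKL+I-BET against RANKL the ranges were 0 to 45 gained and 350 to 1599 lost, and for RANKL+I-BET against untreated 29 to 430 gained and 9 to 152 lost. Fewer libraries make the rule easier to meet.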

Other observations

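The test of unequal covered length and that of another profile in RANKL replicate 2 were chosen only after the results were seen, and the remaining tests were written before. Without the libraries numbered 2, regions at single genes of the osteoclast programme met the rule for gain with RANKL against untreated cells, no more often than expected. Genes nearest to gained regions were 1 of 21 of the NFATc1 axis (Fisher's exact p = 0.716), 2 of 22 of osteoclast function (p = 1) and 1 of 24 of the MYC list (p = 0.726). One lay 1863 bp from Nfatc1 (chromosome 18, 80714935 to 80715621), was held by 2 of 2 RANKL+I-BET libraries and was absent with I-BET alone. One lay 53047 bp from Myc (chromosome 15, 62043409 to 62044777) and was held by 1 RANKL+I-BET library. Others lay within Atp6v1c1, a vacuolar proton pump subunit, and Snx10, a sorting nexin of osteoclasts (chromosome 6, 51551324 to 51552022). Lost regions in this setting included those within Ctsk (chromosome 3, 95503811 to 95503886) and Mitf, a transcription factor of osteoclasts (chromosome 6, 97847777 to 97848854), and 19891 bp from Cebpa, a myeloid transcription factor (chromosome 7, 35098596 to 35099401).

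Of the inflammatory genes nearest to a region gained with RANKL+I-BET against untreated cells in the same setting, Il1rn and Ccl4 were also nearest to one gained with RANKL alone. Camera gave no call for this list (9 of 17 members higher and 8 lower, adjusted p = 0.898). Covered length at Ptgs2, the inducible cyclooxygenase gene, was 0 in all untreated libraries, 0, 1.32 and 0 kb with RANKL and 0.806, 0 and 0.718 kb with RANKL+I-BET. The chemokine gene Ccl2 had 0, 0.177 and 0 kb untreated, 0, 15.4 and 0.665 kb with RANKL and 0.843, 1.28 and 0.570 kb with RANKL+I-BET. With lists as deposited and median-centred and without the libraries numbered 2, limma gave Il1rn a log2 difference of 1.99 (SE 0.42) for RANKL+I-BET against untreated, higher in both RANKL+I-BET libraries used, with a p of 0.0342 adjusted over the list alone and 0.946 over all genes. With the replicate block in addition, limma gave it 1.60 for RANKL against untreated (adjusted p 0.0153 over the list alone and 0.71 over all genes). Omitting the block, no inflammatory list member passed for that comparison. At one covered length without the libraries numbered 2, none passed over the list alone in any comparison.

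RANKL gained 719 regions and lost none. Whether libraries differ only in how much was called stays open, since simulated sets without region-specific effects gave 995.9 gained regions on average (95% between 938 and 1053). The observed number lay below that range, so these sets, whose libraries hold regions independently, did not describe the lists. Whether libraries hold the same regions together was not tested. In covered length around genes, deviations from group means correlated at 0.141 to 0.567 between libraries of the same number. Unequal covered length may account for the excess of gained regions, since without the libraries numbered 2 and at one covered length 1266 were lost and 563 gained, but that reduction also turned the excess round for RANKL+I-BET against RANKL and so decides little. Of the 10 splits of 6 libraries, too few for a share under 0.05, the real one gave 719 regions and the highest other 364, so 1 split in all reached that number.

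For RANKL+I-BET against RANKL the 10 splits are likewise too few for a share under 0.05. The real split gave 347 regions and the highest other 646, so that 2 splits reached the real number. For RANKL+I-BET against untreated the real split gave 36 and the highest other 1110, with 9 splits reaching the real number. The highest set RANKL+I-BET replicates 1 and 3 and untreated replicate 3 against the rest. These are the 3 longest of the lists compared (23.0, 20.6 and 19.5 Mb, against 3.44, 16.1 and 7.79 Mb). List length could therefore give this count, which was not tested. Among the 4 splits that part every pair of the same number, again too few, the highest other gave 182 regions for RANKL against untreated, 323 for RANKL+I-BET against RANKL and 83 for RANKL+I-BET against untreated. For the genes called by limma, all 10 splits gave 0 in each of the 3 comparisons (10 of 10 splits reached the real number, and the highest other was 0).

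The list of RANKL replicate 2 was many times longer than every other list. Deeper sequencing or a laxer threshold of one acetylation profile would leave its highest-ranked peaks at gene ends, yet only 11.7% lay there, against 39.1% to 54.0% in the other 9 libraries, which argues against that explanation. Another profile in that library, such as a mixed sample, another antibody or a mislabelled library, is a candidate explanation, since 6.83% of its highest-ranked peaks overlapped the list of RANKL replicate 3, against 79.1% to 96.7% in the other 8 libraries. Its 2 highest-ranked peaks, chosen after their values were seen, lay within Nkd2 (chromosome 13, 73827779 to 73828000) and Arhgap26 (chromosome 18, 38798222 to 38798898) and overlapped no other list. No biological explanation was tested, and the list covered 82.9% to 95.2% of the peaks of the other lists.

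Peaks on chromosome 8 between 30000001 and 35000000 had high significance for their fold enrichment. This stretch was picked because it ranked highest of 383 stretches of 5 Mb on the measure tested here. Chromosome 3 between 90000001 and 155000000 held 12 of the 40 highest, with library medians of 1.04 to 1.24 times the genome's. The test used the 9 libraries with at least 10 peaks in the chromosome 8 stretch. In 8 of them its median -log10 p at a given fold enrichment exceeded that of every other whole chromosome. In RANKL+I-BET replicate 2 it was 0.969 times the genome's median. A stretch picked for its height would tend to exceed whole chromosomes, so this count decides little. The pattern could come from higher DNA copy number of that stretch in this cell line (raises ChIP and background together), but input reads were not used here and the test does not settle it. No biological explanation was tested.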
